A study of Mus musculus with 6 samples.

How the data were processed

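The deposited table held RPKM values, reads scaled by the length of the gene and by the total of reads assigned to genes, for 6 RNA-seq libraries, 3 of osteoclast precursors (OCP, culture day 3) and 3 of osteoclasts (OC, culture day 6). Per the labels, total RNA was extracted with TRIzol and 2 ug of it went into a stranded mRNA library kit for Illumina sequencing. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.3a and assigned to genes with featureCounts, whose version was not given. The strand setting and the treatment of reads that map to several places were not given in the sources used here, so antisense partners, overlapping genes, paralogs and pseudogenes of a near-identical parent are uncertain. The notes name the human build GRCh38. The coordinates in the table are those of mouse genes. Of its symbols, 95.8% matched GENCODE M21 on GRCm38 and 22340 had the same start and end there, so positions are given as GRCm38. In 24 rows a symbol had been turned into a date, and these rows were kept under that name.

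The RPKM of a gene times its length, per the file headers, gave a whole number of reads for 100% of the values within 0.01 reads. The recovered totals of reads assigned to genes were 42121216, 39705076 and 36740844 for OCP replicates 1, 2 and 3, and 35004451, 33219178 and 38113266 for OC replicates 1, 2 and 3. At a length of 1 kb, 3 reads are worth 0.0712 to 0.0903 RPKM. The 10 most abundant genes took 5.12% to 6.06% of the reads. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 5.18 to 21.4 within groups), so no library was counted as a repeat of another. Any removal of PCR duplicates was not given in the sources used here, and floors cover counting error only.

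Genes with at least 1 RPKM in at least 3 of the 6 libraries were tested. Values were transformed to log2(RPKM + 1), and OC was compared with OCP in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a moderated variance that follows the mean and is robust to outlying genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with 0.05 as the threshold, two-sided. Fold changes are OC minus OCP on this log2 scale, and ratios of means are of untransformed RPKM. The design written for a count table was not used, because the table holds RPKM. Each of 29 gene lists was counted by its members that rose or fell, over all genes tested and adjusted over the list alone, and the 22 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the data. Unless a separate count is given, the count adjusted over the list alone was the same, except that 1 gene of T and NK cells fell over that list alone.

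The comparison, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Sema3a, and the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those with a symbol, an adjusted p under 0.05, groups that do not overlap and a mean of at least 10 RPKM in the higher group. It also named, for each list, its 2 called members with the largest change (4 for semaphorins, plexins and lymphangiogenic factors), the most abundant member of lists of other cells and RNA quality, and the member with the largest change against a called list. Genes outside the rule are said to have been named after their values were seen.

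The alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 RPKM, quantile normalization, TMM factors on RPKM, the fit without trend and robust options, the replicate number as a block, and leaving out each replicate in turn. A voom fit on the recovered whole reads with TMM factors, for genes with at least 10 reads on average where low genes were concerned, and a test of protein-coding genes alone were added after seeing the data. In 5 runs on simulated reads of OC and OCP with 200 changed genes among 12140 tested, the limma steps recovered 91.8% of genes changed 1.5-fold, 96.9% of those changed 2-fold and 99.1% of those changed 4-fold, and 8.62% of the calls were false. Every simulated gene had the same spread beyond counting error (dispersion 0.0021), taken from genes with many reads. The data had 6843 calls, far more than the 200 simulated changes. These shares therefore do not give the power or error rate of the real comparison. Processed pseudogenes were paired with a protein-coding parent by blastn 2.17.0 (at least 85% identity over at least 50% of the length). Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.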

Results

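RNA was sequenced from bone marrow-derived macrophages of C57BL/6 mice aged 8 weeks that had been cultured with macrophage colony-stimulating factor (M-CSF) at 20 ng/ml and RANKL at 10 ng/ml, the cytokine that drives osteoclast formation. The 6 libraries fell into 2 labelled groups of 3. Osteoclast precursors (OCP) were taken on day 3 of culture, and osteoclasts (OC), the multinucleated bone-resorbing cells, on day 6. The table listed 26529 genes, each above 0 in at least 1 library, and the recovered library totals were between 33219178 and 42121216 reads assigned to genes. No label says that replicates came from separate mice or cultures, so the p-values measure the spread between these samples, which may be technical. The group names below are those of the labels. The title of the series names Semaphorin 3A made by osteoclasts and the lymphatic vessels, and the comparison of OC with OCP asks how this gene and the rest of the transcriptome differ between both stages.

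The libraries labelled OC had strongly raised transcripts of inflammatory mediators. Ptgs2, the inducible cyclooxygenase on chromosome 1 (150100031 to 150108227, GRCm38 coordinates), went from 1.21 ± 0.247 RPKM in OCP to 228 ± 13.0 RPKM in OC (SD, n = 3 per group), a 189-fold ratio of means. The chemokine Ccl3 went from 107 ± 0.926 to 3552 ± 249 RPKM, and Csf3, the granulocyte colony-stimulating factor, from 2.96 ± 0.455 to 169 ± 6.67 RPKM. Csf2, the granulocyte-macrophage colony-stimulating factor on chromosome 11 (54247271 to 54249667), was listed at 0 in all 3 OCP libraries and at 54.9 ± 1.5 RPKM in OC. This was at least 1736-fold higher against a floor of 3 reads over the OCP group, a floor that covers counting error only. The reads of Csf2 overlap those of the antisense gene Gm12223, and the use of strand in counting was not given, so they cannot be assigned to one strand. Spink5, a serine protease inhibitor, and Urah were also among the 6 genes with the largest rise, at 45.7 ± 6.24 and 90.6 ± 3.96 RPKM in OC. Their OCP levels were 0.0271 ± 0.0281 and 0.746 ± 0.152 RPKM, and Urah overlaps the antisense gene C330022C24Rik. The falls were smaller. Mt3, a metallothionein on chromosome 8 (94152607 to 94154146), went from 59.3 ± 4.06 to 12.5 ± 1.12 RPKM, and the tropomyosin Tpm2 from 28.6 ± 3.05 to 7.43 ± 0.466 RPKM. Chac1 fell from 16.7 to 4.26 RPKM, Trim54 from 56.8 to 19.6 RPKM, Angpt2 from 20.9 to 6.97 RPKM and Akr1c18 from 121 to 43.8 RPKM. The adjusted p-values of these 12 genes in the limma fit lay between 3.4e-10 for Csf2 and 1.4e-05 for Akr1c18.

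Of 12301 genes tested with limma on log2(RPKM + 1), 2889 were higher and 3954 lower in OC at an adjusted p under 0.05. The balance turned with TMM factors, which gave 3471 genes higher and 3224 lower. At least 2-fold differences were seen for 453 higher and 54 lower genes, on a scale whose pseudocount understates the change of genes with low values. With a pseudocount of 0.1 the count of genes at least 2-fold lower was 164, and with the read-based fit it was 160 lower and 732 higher. The values of all OC libraries lay apart from those of all OCP libraries in 7713 of the 12301 tested genes, where chance gives 10% for 3 against 3. The correlation of log2(RPKM + 1) was 0.994 to 0.995 between libraries of a group and 0.949 to 0.956 between groups.

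Genes of the osteoclast resorption machinery were lower in the libraries labelled OC. Of 20 tested members of this list, 18 fell (19 adjusted over the list alone), 1 rose and 1 did not pass the test, with a median log2 fold change of -0.80. Slc4a2, the anion exchanger of the resorbing cell, fell from 83.0 ± 6.00 to 39.0 ± 1.29 RPKM (log2 fold change -1.07, SE 0.06), and Rab38 from 38.5 ± 1.29 to 18.3 ± 1.36 RPKM (-1.04, SE 0.06). The single member that rose was the cathepsin Ctsb, from 272 ± 6.76 to 406 ± 17.9 RPKM. Named after their values were seen, the collagen-degrading protease Ctsk fell from 3249 to 1711 RPKM and Acp5, which encodes the tartrate-resistant acid phosphatase, from 642 to 338 RPKM. The list stood apart from other genes by camera (adjusted p = 9.0e-07), and this call was lost at adjusted p = 0.089 with an estimated correlation. Subunits of the V-ATPase, the proton pump, fell in 15 of 18 cases and rose in 1 (adjusted p = 4.3e-05, and adjusted p = 0.081 with an estimated correlation). Atp6v0d2 fell from 334 ± 25.1 to 184 ± 10.4 RPKM and Atp6v1b2 from 236 ± 2.21 to 138 ± 3.59 RPKM, whereas Atp6v0a1 rose from 7.99 ± 0.118 to 10.9 ± 1.04 RPKM. These falls went with rises of macrophage, neutrophil and immediate early genes, whose values are given below.

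The other osteoclast lists were mixed. Among 16 tested fusion genes 9 fell and 5 rose, and the list as a whole did not pass (camera adjusted p = 0.39). Siglec15, a receptor of osteoclast fusion, fell from 14.2 ± 2.36 to 7.05 ± 1.28 RPKM, while the tetraspanin Cd81 rose from 2.18 ± 0.336 to 5.92 ± 0.246 RPKM. Of 24 tested transcription regulators 10 fell and 7 rose (adjusted p = 0.68). The AP-1 factor Fosl1 rose from 2.71 ± 0.452 to 13.4 ± 0.525 RPKM, and Jdp2 fell from 1028 ± 73.1 to 574 ± 26.3 RPKM. Nfatc1, the master regulator of osteoclast formation, named after its values were seen, fell from 94.8 to 61.6 RPKM. Negative regulators of osteoclast differentiation rose in 11 of 18 cases and fell in 2 (adjusted p = 0.00025, and adjusted p = 0.073 with an estimated correlation). Irf8 rose from 10.6 ± 0.176 to 23.8 ± 1.06 RPKM and Rbpj from 12.9 ± 0.531 to 28.4 ± 1.09 RPKM, and Id3 went the other way, from 2.25 ± 0.555 to 1.24 ± 0.160 RPKM.

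Macrophage and monocyte markers rose in 18 of 22 tested cases and fell in 3 (median log2 fold change 0.79, camera adjusted p = 7.8e-07, and adjusted p = 0.073 with an estimated correlation). The fractalkine receptor Cx3cr1 went from 0.833 ± 0.0955 to 4.19 ± 0.302 RPKM and the scavenger receptor Cd36 from 10.3 ± 1.61 to 27.1 ± 2.59 RPKM, while Cd68 fell from 854 ± 31.3 to 721 ± 20.9 RPKM. Inflammatory cytokines and chemokines rose in 19 of 25 cases and fell in 4, with 13 at least 2-fold higher (adjusted p = 4.3e-09, and adjusted p = 0.081 with an estimated correlation). Ccl12 had the largest fall among them, from 51.7 ± 3.33 to 39.0 ± 2.44 RPKM. Genes of antigen presentation by MHC class II rose in 8 of 11 cases and fell in 2 (adjusted p = 0.0021, and adjusted p = 0.081 with an estimated correlation). The invariant chain Cd74 rose from 36.0 ± 1.54 to 150 ± 6.64 RPKM and the costimulatory Cd80 from 0.512 ± 0.188 to 2.31 ± 0.361 RPKM, against a fall of Ifi30 from 227 ± 10.3 to 162 ± 5.76 RPKM. Interferon-stimulated genes rose in 16 of 30 cases (17 adjusted over the list alone) and fell in 8 (adjusted p = 0.013, and adjusted p = 0.29 with an estimated correlation). Ifi44 and Irf7 rose to 4.30 ± 0.298 and 208 ± 8.33 RPKM from 1.23 ± 0.105 and 99.8 ± 4.57 RPKM, and Ifi35 fell from 50.3 ± 2.45 to 37.7 ± 1.99 RPKM. Neutrophil markers, with 6 of 7 risen, and heat shock and immediate early genes, with 12 of 16 risen, moved with these lists.

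**Figure D1:**
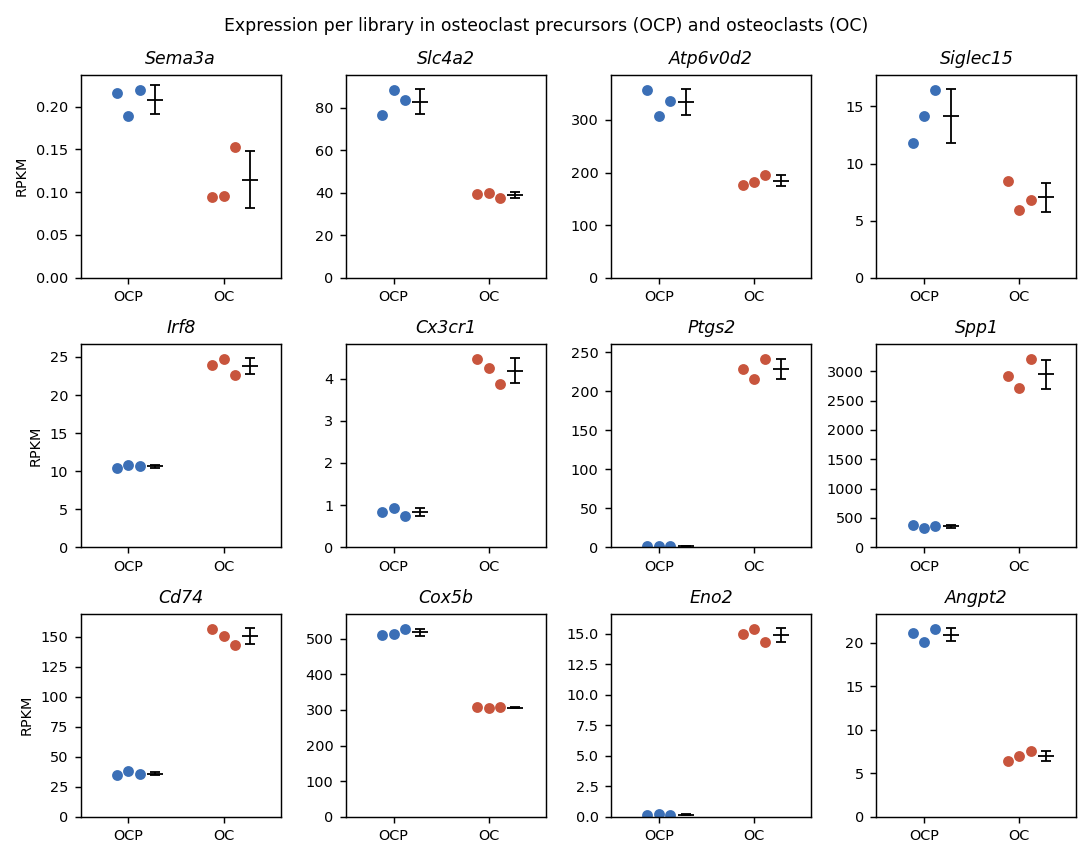
RPKM of 12 named genes in each library of osteoclast precursors (OCP, blue) and osteoclasts (OC, red). The black bar beside each group is its mean ± SD (n = 3), and each vertical axis starts at 0 with its own scale. Slc4a2, Atp6v0d2, Siglec15, Cox5b, Angpt2 and Sema3a were lower in each OC library than in any OCP library, and Irf8, Cx3cr1, Ptgs2, Spp1, Cd74 and Eno2 higher.

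Sema3a, which encodes a secreted axon guidance and vessel-patterning ligand and lies on the plus strand of chromosome 5 (13125414 to 13602565), had a low RPKM in both groups, at an exon length of 13868 bases. The OCP libraries held 126, 104 and 112 reads over its exons and the OC libraries 46, 44 and 81 reads. Its level was 0.208 ± 0.0168 RPKM in OCP and 0.115 ± 0.0336 RPKM in OC (SD, n = 3), so it failed the filter of 1 RPKM. In the unfiltered limma fit its log2 fold change of RPKM + 1 was -0.12 (SE 0.05), which did not pass (adjusted p = 0.12). The pseudocount of 1 understates a change at this level, and the log2 fold change was -0.53 with a pseudocount of 0.1 and -0.84 with 0.01. Sema3a passed with a lower value after quantile normalization (adjusted p = 0.039), without the trend and robust options (adjusted p = 0.039) and in the read-based voom fit, which was added after seeing the data (log2 fold change -0.82, SE 0.21, adjusted p = 0.0016). Over its other alternatives the adjusted p ranged from 0.11 to 0.26.

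The semaphorins as a list did not pass (camera adjusted p = 0.53). Of 6 tested members 3 fell (4 adjusted over the list alone) and 1 rose. Sema4d, an osteoclast-derived inhibitor of bone formation, fell from 46.9 ± 1.37 to 31.6 ± 1.06 RPKM and Sema7a from 10.7 ± 0.5 to 7.82 ± 0.489 RPKM. Sema4a rose from 3.24 ± 0.139 to 5.92 ± 0.268 RPKM. Sema4b fell from 1.92 ± 0.0975 to 1.49 ± 0.191 RPKM (adjusted p = 0.034). This call was lost under TMM scaling (adjusted p = 0.074), with no filter on low values (adjusted p = 0.069) and with the replicate number as a block. It was also lost without OC replicate 1 or 2 or any of the OCP replicates (adjusted p from 0.062 to 0.10). The list of plexins and neuropilins, the semaphorin receptors, also held L1cam. Its members rose in 5 of 9 cases and fell in 2 (camera adjusted p = 0.35). Plxnd1 fell from 128 ± 4.90 to 79.5 ± 3.67 RPKM and Plxna4 from 7.39 ± 0.134 to 4.29 ± 0.132 RPKM. Plxnb2 rose from 55.9 ± 2.76 to 75.9 ± 2.44 RPKM and L1cam from 0.95 ± 0.0204 to 1.67 ± 0.0763 RPKM. L1cam overlaps exons of Arhgap4 on the same strand, so its value is uncertain. Lymphangiogenic and angiogenic factors rose in 7 of 13 tested cases and fell in 3 (adjusted p = 0.092). Adm, which encodes adrenomedullin, rose from 0.387 ± 0.0300 to 4.74 ± 1.04 RPKM, Edn1 from 0.872 ± 0.142 to 2.81 ± 0.345 RPKM and the placental growth factor Pgf from 11.7 ± 0.769 to 21.7 ± 1.8 RPKM. Angpt2, the angiopoietin on chromosome 8 (18690263 to 18741562), fell from 20.9 ± 0.773 to 6.97 ± 0.568 RPKM. Factors that couple osteoclasts to osteoblasts went both ways, with 6 risen and 6 fallen of 14 tested (adjusted p = 0.60). Their median log2 fold change was -0.01 and their mean 0.24. Spp1, which encodes osteopontin, rose from 359 ± 26.5 to 2946 ± 244 RPKM, and Il1b from 18.7 ± 1.65 to 56.7 ± 3.81 RPKM.

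All 48 tested genes of oxidative phosphorylation fell, with a median log2 fold change of -0.53 (camera adjusted p = 1.5e-13, and adjusted p = 0.073 with an estimated correlation). Under TMM factors 44 of them passed, and all 48 kept a lower value. Cox5b fell from 518 ± 9.35 to 307 ± 1.59 RPKM and Ndufa4 from 42.6 ± 4.87 to 25.0 ± 1.79 RPKM. Mitochondrially encoded genes fell in 10 of 13 cases and rose in 1 (adjusted p = 0.020, and adjusted p = 0.57 with an estimated correlation). The most abundant over all 6 libraries, mt-Nd4l, fell from 1975 ± 300 to 1464 ± 95.3 RPKM, and mt-Co1 rose from 1264 ± 232 to 1991 ± 47.6 RPKM. Genes of glycolysis rose in 13 of 20 cases and fell in 2 (adjusted p = 8.8e-05, and adjusted p = 0.42 with an estimated correlation). The neuronal enolase Eno2 rose from 0.173 ± 0.0477 to 14.9 ± 0.573 RPKM and the glycolytic regulator Pfkfb3 from 16.2 ± 0.840 to 65.5 ± 0.628 RPKM, while Pfkm fell from 12.5 ± 0.728 to 8.61 ± 0.345 RPKM. Cholesterol biosynthesis genes fell in 11 of 20 cases and rose in 0, but the list did not pass (adjusted p = 0.054). Pmvk fell from 84.6 ± 3.98 to 55.8 ± 1.8 RPKM and Mvk from 6.23 ± 0.451 to 4.41 ± 0.130 RPKM. Of 34 lysosomal genes 14 rose and 8 fell (adjusted p = 0.064), among them Ppt1, from 15.6 ± 0.761 to 34.9 ± 0.401 RPKM, and Lamp2, from 4.09 ± 0.160 to 9.75 ± 0.441 RPKM.

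Genes of the cell cycle and mitosis fell in 18 of 38 cases and rose in 2 (adjusted p = 0.0018, and adjusted p = 0.15 with an estimated correlation). The mitotic kinase Plk1 fell from 10.8 ± 0.527 to 5.51 ± 0.469 RPKM and Cdc20 from 10.2 ± 0.531 to 5.63 ± 0.539 RPKM. Pcna rose from 25.2 ± 2.62 to 29.7 ± 1.39 RPKM (adjusted p = 0.030), a call that was lost with no filter on low values (adjusted p = 0.082) and without any of the OC replicates or OCP replicate 2 or 3 (adjusted p from 0.053 to 0.11).

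Among markers of cells other than macrophages, neutrophil genes rose in 6 of 7 tested cases (adjusted p = 0.0030, and adjusted p = 0.17 with an estimated correlation). Lcn2, which activated macrophages also express, went from 31.7 ± 1.48 to 95.7 ± 2.04 RPKM. The lists of stromal, endothelial, B cell, T and NK cell, erythroid and megakaryocyte, dendritic and mast cell markers each had fewer than 5 tested genes and got no list test. Their most abundant members were Acta2 at 1.22 ± 0.0660 and 1.19 ± 0.275 RPKM in OCP and OC, Pdpn at 44.8 ± 2.29 and 91.7 ± 2.28, Blnk at 5.63 ± 0.0615 and 5.99 ± 0.456, Trac at 1.81 ± 0.322 and 1.26 ± 0.375, Pf4 at 36.1 ± 0.567 and 89.2 ± 1.09, Batf3 at 1.09 ± 0.158 and 0.995 ± 0.153, and Mcpt1 at 0.928 ± 0.243 and 0.336 ± 0.159 RPKM. Of these Pdpn and Pf4 passed the test, both higher in OC. Mcpt1 was under the filter and not tested, and in the added read-based voom fit it was lower in OC (log2 fold change -1.52, adjusted p = 0.0030). The only other called members of these lists, named after their values were seen, were the T cell genes Lck, which rose from 0.131 ± 0.0678 to 1.23 ± 0.0463 RPKM, and Il7r, which rose from 0.973 ± 0.252 to 1.42 ± 0.210 RPKM, and the B cell gene Vpreb1, which fell from 3.80 ± 0.362 to 2.91 ± 0.254 RPKM. Heat shock and immediate early genes, which respond to stress and handling, rose in 12 of 16 cases and fell in 1 (camera adjusted p = 6.4e-06, and adjusted p = 0.073 with an estimated correlation). Of those that rose, 5 were at least 2-fold higher. The most abundant member, Hspa8, went from 752 ± 20.7 to 909 ± 19.1 RPKM, and Dnajb1 fell from 30.5 ± 1.68 to 26.0 ± 0.510 RPKM. Cytosolic ribosomal protein genes rose in 8 and fell in 6 of 36 cases (adjusted p = 0.26), with Rpl19 at 2290 ± 78.2 RPKM in OCP and 2250 ± 99 RPKM in OC.

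**Figure D2:**
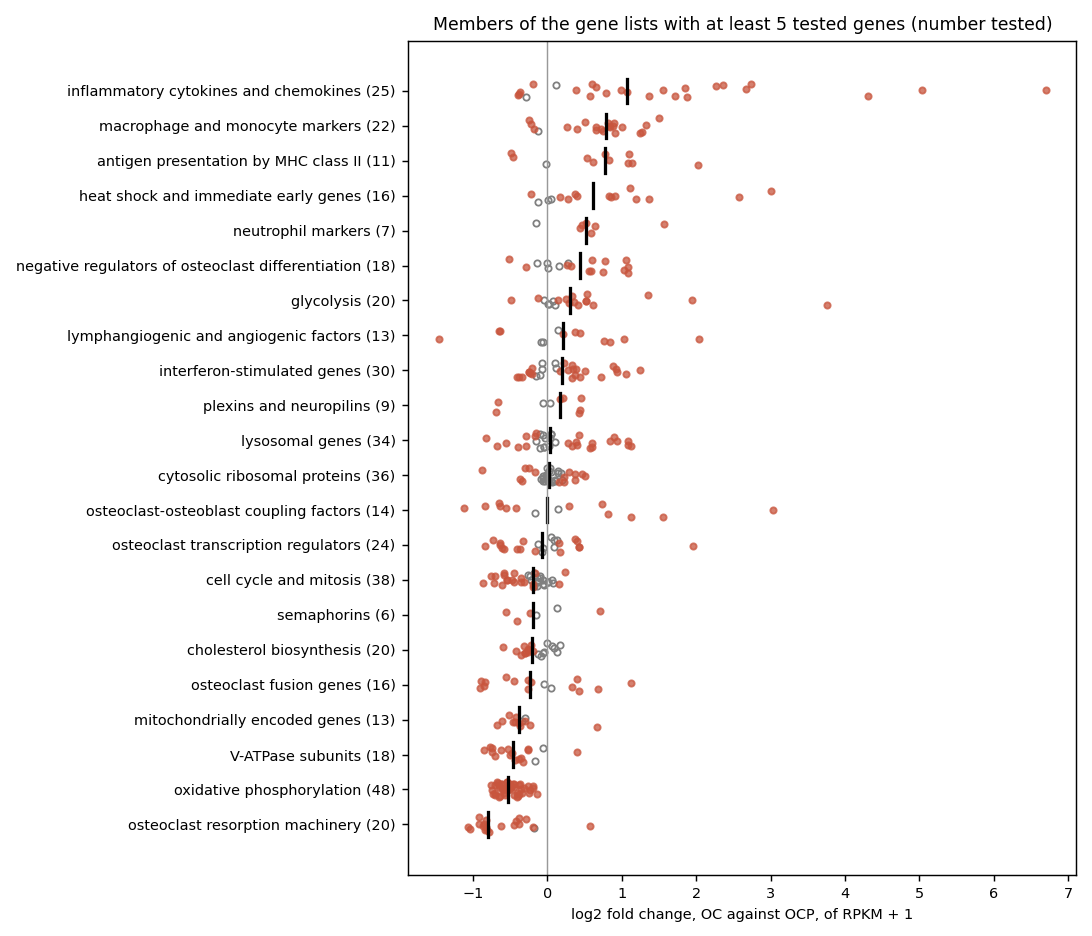
Log2 fold change of RPKM + 1 in OC against OCP for each tested member of the 22 lists with at least 5 tested genes, sorted by list median (black line). Filled red points passed an adjusted p under 0.05 and open grey points did not. The medians run from -0.80 for the resorption machinery to 1.07 for inflammatory cytokines and chemokines.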

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

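The voom fit on recovered reads and the test of protein-coding genes alone were chosen after seeing the data. None of the 6843 called genes was called in the opposite direction under any of the 16 settings in which it was tested, and no named gene or list that passed turned its direction. Genes at least 2-fold higher numbered 238 with a mean of at least 5 RPKM, 268 among protein-coding genes and 732 by voom, against 453, and those at least 2-fold lower 35, 34 and 160, against 54. The lower count was 164 with a pseudocount of 0.1 and 185 with 0.01, where low genes are shrunk less. With a mean of at least 5 RPKM 1645 genes were higher, against 2889, among 7228 tested. Fewer genes were tested under both filters; the cause of the other changes was not tested. TMM factors gave 3471 genes higher and 3224 lower. The log2 fold change of Sema3a was -0.16 after quantile normalization, -0.12 without trend and robust options and -0.82 by voom, past the threshold in these 3 settings (adjusted p 0.039, 0.039 and 0.0016). Without trend and robust options its log2 fold change equalled that of the main settings, and only its SE was smaller, at 0.03 against 0.05. Why it passed after quantile normalization and by voom was not tested. With an estimated correlation 0 of the 22 lists passed in camera, against 13 with the preset one, and 8 had an unadjusted p under 0.05. The lowest adjusted p was 0.073. The lists of lysosomal and cholesterol genes passed in some settings, and the mitochondrially encoded list was lost at a mean of at least 5 RPKM (adjusted p = 0.057). Leaving out one replicate gave 2524 to 2932 genes higher and 3370 to 3784 lower. Whether the replicate numbers pair the samples could not be told. Correlations of deviations were -0.11, 0.14 and 0.01 for same-numbered samples and ranged from -0.28 to 0.26 for the others. A fit with the replicate block gave 2827 genes higher and 3851 lower, and Sema4b no longer passed (adjusted p = 0.064) while Trac did (adjusted p = 0.013). Of the named genes, Sema4b, Pcna and Trac crossed the threshold in some settings, Sema4b and Pcna both with no filter (adjusted p 0.069 and 0.082). Another count model, other size factors and voom on deposited counts, chosen in advance for a count table, were not run, because the table holds RPKM. The minimum of 1 RPKM left out Sema3a. The size of its log2 fold change depended on the pseudocount, at -0.12 with 1, -0.53 with 0.1 and -0.84 with 0.01, and it did not pass with any of them. By reads, 2 semaphorins rose and 5 fell of 12.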

Other observations

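All tests of explanations below were chosen only after the results were seen. Genes nearly silent in OCP and clearly expressed in OC were found in one direction. Above 5 RPKM on average in OC and below 0.3 RPKM in OCP were 31 genes, 17 of them protein-coding, and 0 genes showed the reverse. The following genes were named after their values were seen. The 31 genes are not independent of one another. They include Gm12223 and C330022C24Rik, antisense to Csf2 and Urah, processed pseudogenes such as the Odc1 copy Gm17709, and the class I MHC genes H2-Q2 and H2-Q10. The transcription factor Mycn was at 0.00551 RPKM in OCP and 16.2 RPKM in OC, the homeobox gene Irx2 at 0.0155 and 6.26 RPKM, and Rhox2h, a homeobox gene of the X chromosome, was listed at 0 in each OCP library and at 12.1 RPKM in OC. The chromatin protein gene Hmga2 rose from 0.588 to 7.98 RPKM. Odc1, the rate-limiting enzyme of polyamine synthesis and a known target of MYC factors, rose from 82.5 to 1583 RPKM, and Phgdh, the first enzyme of serine synthesis, from 25.2 to 72.1 RPKM. Of the class I MHC genes of the Q region, H2-Q6 rose from 2.14 to 57.7 RPKM and H2-Q4 from 7.21 to 56.0 RPKM, and values of genes this similar in sequence are uncertain.

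The 6843 called genes were set against the other splits of the 6 libraries into 3 and 3. The real split alone, 1 of the 10, gave that many calls, and the highest of the others gave 0. For the 507 genes changed at least 2-fold the real split was again 1 of 10, with 0 as the highest other. With 10 splits no share under 0.05 is possible.

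The first pattern is that osteoclast effector genes were lower in the libraries labelled osteoclasts, with a median log2 fold change of -0.80 for the resorption list. The tables argue against scaling, since the median nearest 0 over 3 other scalings was -0.73. For RNA of stromal, endothelial, lymphoid or erythroid cells, 8 chosen abundant genes summed to 3.16 RPKM in OC and 3.07 RPKM in OCP. These values argue against such RNA only as far as the 8 genes show it. Left out of the 8 were Pdpn, Pf4, Lck and Il7r of the lists of these cells, which rose, and Vpreb1, which fell. Neutrophil RNA, with 6 of 7 markers risen, was not tested as a source. The low resorption list (-0.80) cannot test an exchange of the group labels, because it is the pattern itself. The cell cycle list, of which 18 of 38 genes fell and 2 rose in OC, was not used to judge it. A larger share of macrophage-like RNA in the OC cultures may also account for the low resorption list. The macrophage list had a median of 0.79, and 3 of its 22 genes fell. An exchange of labels would raise the macrophage list as well, so this list does not separate the macrophage share from an exchange. The exchange and the macrophage share stay open, as does a biological change between day 3 and day 6 of culture, which was not tested.

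The second pattern concerns processed pseudogenes. Of 734 tested, 626 were paired with a parent, and 45 of these copies were at least 2-fold higher in OC. Among all 12301 tested genes 453 were at least 2-fold higher. A difference in the assignment of multi-mapping reads that shifts most copies is hard to reconcile with their median log2 fold change. It was -0.0083 over all 249 copies of at least 99% identity, 18 of which were at least 2-fold higher. This median cannot show a difference confined to some of the copies. The identity may also hold over as little as 50% of a copy's length. Reads moved between parent and copy remain a candidate explanation for part of these copies. Of 7 tested parents, not themselves 2-fold higher, whose copies at least 2-fold higher gained at least 10% of the parent's reads, 5 fell. Among 315 parents of copies not called at least 2-fold higher, 36.5% fell. This set overlaps the 7 and includes parents at least 2-fold higher, so both shares are not strictly comparable. The parent Rpl3, which did not pass the test, was 91.4 CPM higher, and its copies at least 2-fold higher gained 222 CPM. Hist2h2aa1, which also did not pass, lost 0.53 CPM, less than the 5.13 CPM that its copy gained. Parents at least 2-fold higher were left out of the 7. Among them was Odc1, whose 7 copies at least 2-fold higher gained 1172 CPM while the parent gained 3823 CPM. A sequence background of the OC cells that differs from that of the OCP cells cannot be told apart from other causes, because the reads were not used here and the 31 genes nearly silent in OCP do not decide it.

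The third pattern is the fall of oxidative phosphorylation genes. The tables argue against gene length and GC content, because the median of the 48 genes was -0.52 after the trend over both was taken out, and the ribosomal protein genes, of similar median length (1800 against 1870 bases), then had a median of 0.06. They argue against scaling too, which left a median of -0.46 at the value nearest 0 over 3 other scalings. A biological difference between the culture days is a hypothesis that these tests leave open. So are the exchange of labels and the macrophage share (median 0.79) named for the first pattern, which the lists could not tell apart.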
